A study of Mus musculus with 54 samples.

How the data were processed

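RNA of mouse testis and ovary was sequenced from F1 animals exposed to a control solution or to 1 of 2 doses of a pharmaceutical cocktail, and from F2 animals of 6 parental crosses. The labels describe a stranded mRNA ligation kit and reads of 100 nt. There were 54 libraries in 18 groups of 3, and the F2 groups were taken from the parents' groups, since the labels state no dose for the F2 animals themselves. The control water held 0.001% ethanol. Dose 1 was 11.3 ng/L ibuprofen, 90 ng/L 2-hydroxyibuprofen, 22.5 ng/L diclofenac and 2.25 ng/L ethinyl-estradiol, and dose 2 was 113, 225, 112 and 45 ng/L in the same order.

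The deposited tables hold raw read counts per gene, which the authors did not normalize, for 26264 genes in 27 libraries of each tissue. The submitters' processing notes name bcl2fastq 2.20, FastQC 1.19, TopHat2 2.1.1, Bowtie2 2.4.5, SAMtools 1.13, featureCounts 2.0.3 and DESeq2 1.32.0 with the mouse genome build mm39. The annotation and the strand setting of the counting are not given in the sources used here, so values of antisense or overlapping genes and of pseudogenes and paralogs are uncertain, and no coordinates are given. Every column was mapped to a sample (0 left over). Total counts per library, with M for mega, were 31.8 to 122.4 M in F1 testis (median 41.8, the highest in dose 1 C), 31.6 to 48.2 M in F2 testis (median 38.2), 36.6 to 57.4 M in F1 ovary (median 45.5) and 37.9 to 84.7 M in F2 ovary (median 42.9, the highest in control cross C). Replicate libraries were checked for duplication, and their counts differed by more than counting error in every group, with a lowest chi-square per degree of freedom of 7.13 over genes with at least 10 counts in both.

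Counts were fitted with edgeR 4.0.16 under R 4.3.3, with a separate fit for each tissue and generation (9 libraries in F1, 18 in F2) and group means as the design. Scaling factors were from the trimmed mean of M values (TMM), genes were filtered with filterByExpr at a minimum count of 10, and quasi-likelihood F tests were adjusted by the Benjamini-Hochberg method at 0.05. This left 19025 genes in F1 testis, 19379 in F2 testis, 17896 in F1 ovary and 17400 in F2 ovary. There were 20 comparisons, 14 of them with the control of the same tissue and generation and 6 direct tests between doses or between maternal and paternal crosses of 1 dose. Log2 CPM used a prior count of 2. With 3 libraries against 3 an exact permutation test of a single value cannot give a p under 0.1, so none was used for single genes. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, for lists with at least 3 measured members, adjusted over the lists of a comparison, and again with a correlation estimated for each list. There were 38 lists of pathways and cell markers, written with the tests, the alternatives and the rule for named genes before the data were examined. The list of mitochondrial genome transcripts could not be tested, because the tables hold 0 of them.

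Named genes followed a rule. Among genes that passed, whose 3 exposed libraries all lay above or all below the 3 reference libraries, and with a mean of at least 1 CPM in the higher group, those with the largest changes were taken: up to 10 in each direction for F1 doses and the biparental cross, and up to 5 for other comparisons. List members that passed were added. Symbols of predicted genes and clone names were counted but not named unless fewer than 3 others qualified; all genes were named where fewer than 5 passed, and the 3 with the lowest p where none passed. In the maternal dose 2 cross of F2 testis 71 of 72 genes met the separation and level criteria, and 38 of 39 in the paternal dose 1 cross. Star, Cyp11a1, Cyp17a1, Hsd3b1, Cyp19a1, Esr1, Esr2, Ptgs1 and Ptgs2 were named in every comparison with a control; Ptgs2 was not tested in testis. Some further genes are not reported.

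The procedure was tested on simulated data with 200 changed genes and a list of 25 genes moved 1.5-fold, from seed 101. Of the genes changed 2-fold and 4-fold, 23% and 90% were recovered with the spread of F1 testis, 79% and 97% with F2 testis, 62% and 82% with F1 ovary and 60% and 97% with F2 ovary. False calls were 5 of 18652, 4 of 18979, 10 of 17558 and 12 of 17051 unchanged genes in the same order. The moved list was called in the right direction in all 4 settings, and an unmoved list in none. Simulated genes were drawn independently of each other, so this does not test list calls where members are correlated.

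Alternatives were relative log expression (RLE) size factors, no filter on low counts, DESeq2 1.42.0, the replicate letter as a block, only the 6 libraries compared, all 27 libraries of a tissue, and leaving out each library in turn. After the data were examined, fits without libraries that stand apart were added. RLE in place of TMM moved the median log2 fold change of all genes by at most 0.0123. Overlaps of called genes were set against n1 × n2 / N and against 100 simulations in which comparisons share only their controls (seed 606), and within-group correlations against 1000 random gene sets (seed 707). Shares of testis RNA used genes above 50 CPM in testis and below 0.5 CPM in F2 ovary, and 8 Y-linked genes.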

Results

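Drinking water carried a cocktail of ibuprofen, 2-hydroxyibuprofen, diclofenac and ethinyl-estradiol at 2 doses from 8.5 days post coitum, and the question was whether it changed gene expression in F1 gonads. A further question was whether F2 gonads differed by the parent that came from an exposed group. Testes were taken at 35 and ovaries at 30 days post partum, with 3 libraries in each of 18 groups. The F2 labels give only the groups of the father and the mother. The maternal dose 1 cross had a control father and a dose 1 mother, the paternal dose 1 cross a dose 1 father and a control mother. The dose 2 crosses are named in the same way, and in the biparental dose 2 cross both parents came from the dose 2 group. Levels are library-scaled counts (CPM) as mean ± SD with n = 3 per group, and changes are log2 fold changes. The labels do not state whether replicates are separate animals or whether they come from separate litters. If a group came from a single litter, litter could not be told apart from dose or cross. The p-values therefore measure the spread between these samples, and n = 3 limits confidence in every comparison. Chance alone would put 951 genes at an unadjusted p under 0.05 in each F1 testis comparison, 969 in F2 testis, 895 in F1 ovary and 870 in F2 ovary.

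In the F1 testis at dose 1, Crtam, which encodes a surface molecule of cytotoxic T and natural killer cells, was at 34.4 ± 3.84 CPM against 2.92 ± 0.285 in controls (n = 3 each). It rose by 3.56 (edgeR adjusted p = 0.000104). Cck, a gut hormone and neuropeptide gene, had counts of 4, 1 and 1 at dose 1 and 5.60 ± 2.47 CPM in controls (log2 change -7.27, edgeR adjusted p = 0.00934), a fold that depends on the prior count. The pseudogene Alms1-ps2 was at 0.288 ± 0.0862 CPM against 2.62 ± 0.295 and fell by 3.15 (edgeR adjusted p = 0.00339). Gm11166 was at 2.397 ± 0.223 CPM against 16.9 ± 2.13 and fell by 2.81 (edgeR adjusted p = 0.00339). These 4 genes, 1 higher and 3 lower, were the genes that passed, with 605 at an unadjusted p under 0.05 (408 higher and 197 lower), fewer than the 951 of chance, and 27 by DESeq2. In 12.4% of genes the 3 dose 1 libraries did not overlap the controls, where chance gives 10%. The count was 8 with the 6 libraries alone, 7 without control B, 2 without dose 1 B and 1 without dose 1 C, where Crtam was the gene left. Cck had an edgeR adjusted p = 0.0908 without dose 1 B and 0.066 without dose 1 C. The 5 genes called in F1 testis at either dose also varied within single groups of F2 testis. Crtam, for example, ran from 2.42 to 33.9 CPM within the paternal dose 1 cross.

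Among gene lists in the F1 testis at dose 1, interferon response genes had a median change of 0.44, with 21 of 23 members higher (camera adjusted p = 0.000123; adjusted p = 0.586 with an estimated correlation). Sertoli cell markers had a median of -0.16, with 22 of 27 members lower (camera adjusted p = 0.0357; adjusted p = 0.59 with an estimated correlation). Adipocyte markers had a median of -0.38 and round spermatid markers a median of 0.10 (camera adjusted p = 0.0357 and 0.0432; adjusted p = 0.586 and 0.59 with an estimated correlation). No member of these lists passed edgeR over all genes or adjusted over the list alone. Protamine 1 (Prm1) is a spermatid gene named after its values were seen. It ran from 1275 CPM in dose 2 B to 5767 CPM in dose 1 B across the F1 testis libraries, and from 1501 to 1955 CPM in F2. Of the 4 list calls, 1 remained without control A, 3 without control B, 2 without dose 1 A, 3 without dose 1 B and 1 without dose 1 C.

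In the F1 testis at dose 2, P2rx5, an ATP-gated ion channel gene, was at 12.9 ± 1.74 CPM against 1.07 ± 0.304 in controls (n = 3 each), a rise of 3.60 (edgeR adjusted p = 0.0013). It was the gene that passed, with 368 at an unadjusted p under 0.05, fewer than the 951 of chance, and 5 by DESeq2. The groups did not overlap in 4.11% of genes, against 10% by chance. Ribosomal protein genes had a median of 0.35, with 27 of 29 members higher (camera adjusted p = 0.00553; adjusted p = 0.875 with an estimated correlation). Steroidogenesis genes had a median of 0.18, with 19 of 21 members higher, and adipocyte markers a median of 0.53 (camera adjusted p = 0.046 and 0.0459; adjusted p = 0.657 for both with an estimated correlation). No member of these lists passed over all genes. Dose 2 B and dose 2 C stood apart from the other F1 testis libraries on the first principal component, at -58.5 and 77.5. Without both, an alternative chosen after the data were seen, 8 genes passed at dose 1. The dose 2 group then held dose 2 A alone, and adipocyte markers had the opposite direction at dose 2. Without dose 2 C, ribosomal protein genes had an adjusted p of 0.439 by camera and the opposite direction, and the gene count was 4; it was 2 without control B and 2 without dose 2 B. Of the 3 list calls, 2 remained without control A and 2 without control B, and 1 remained without control C, dose 2 A, dose 2 B or dose 2 C.

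**Figure D1:**
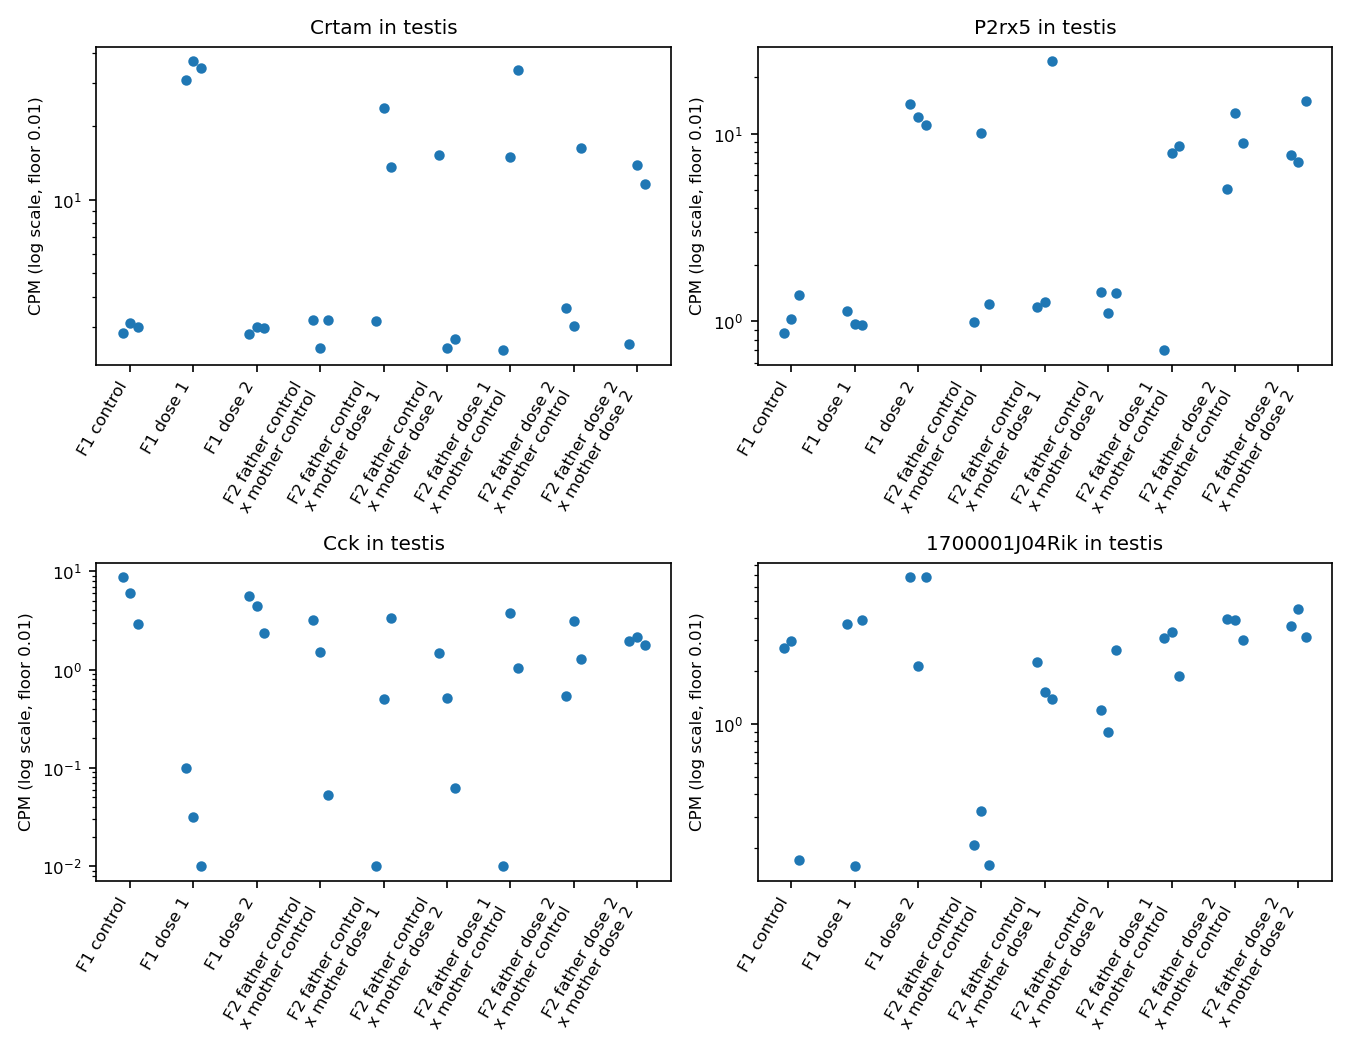
Levels of Crtam, P2rx5 and Cck, called in F1 testis, and of 1700001J04Rik, called in F2 testis but not in F1. Values are in CPM on a log axis, with those under 0.01 drawn at 0.01. Each testis library is 1 point, and libraries are grouped by F1 exposure or F2 cross. Crtam in the 3 F1 dose 1 libraries lies between 30.8 and 36.8 CPM and in the F1 controls between 2.85 and 3.12 CPM, while the paternal dose 1 cross runs from 2.42 to 33.9 CPM.

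A direct test of dose 2 against dose 1 in F1 testis asked whether the doses differed. P2rx5 (12.9 ± 1.74 against 1.03 ± 0.0769 CPM, log2 change 3.66, edgeR adjusted p = 0.000564) and Alms1-ps2 (2.93 ± 0.326 against 0.288 ± 0.0862 CPM, log2 change 3.31, edgeR adjusted p = 0.00199) were higher at dose 2. Crtam was lower at dose 2 (3.03 ± 0.456 against 34.4 ± 3.84 CPM, log2 change -3.51, edgeR adjusted p = 0.000116). Cck was higher at 4.15 ± 1.43 CPM (edgeR adjusted p = 0.0126) but had an edgeR adjusted p = 0.115 without dose 1 B, 0.0978 without dose 1 C and 0.0575 without dose 2 A. In all, 5 genes passed, 4 higher and 1 lower, with 630 at an unadjusted p under 0.05 (282 higher and 348 lower) and 23 by DESeq2; 3 passed without dose 1 C. Interferon response genes had a median of -0.35 (camera adjusted p = 5.24e-06) and adipocyte markers of 0.67 (camera adjusted p = 5.24e-06), while the lowest adjusted p of any list was 0.296 with an estimated correlation.

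In the F2 testis of the maternal dose 2 cross, Kcnq1ot1, a paternally expressed imprinted long non-coding RNA, was at 99.1 ± 8.99 CPM against 185 ± 25.9 in the control cross (n = 3 each) and fell by 0.90 (edgeR adjusted p = 0.00651), the 1 member of the imprinted list that fell. Lars2, a mitochondrial leucyl-tRNA synthetase gene, was at 850.2 ± 308 CPM against 3383 ± 484 and fell by 1.99 (edgeR adjusted p = 0.0187). Malat1, a nuclear-retained long non-coding RNA, and Rn45s, the ribosomal RNA precursor, were named after their values were seen and fell by 1.56 and 0.68 (edgeR adjusted p = 0.00613 and 0.00835). The maternal dose 2 libraries had Malat1 at 267 to 373 CPM and Rn45s at 138 to 169 CPM. Unexposed F1 testis controls overlapped these levels, with Malat1 at 104 to 473 CPM and Rn45s at 161 to 229 CPM. Further RNAs that fell were Mir7241, Tbrg3, Pcdha5 and Lncpint, by 1.99 to 3.03. Cdkn2a, which encodes cell-cycle inhibitors, rose by 0.83 (4.24 ± 0.615 against 2.395 ± 0.442 CPM, edgeR adjusted p = 0.0343). Tuba3a rose by 0.41 (edgeR adjusted p = 0.0195) and Aaas, a nuclear pore gene, by 0.42 (edgeR adjusted p = 0.0214). In all, 10 genes rose and 62 fell, with 3052 at an unadjusted p under 0.05 (1602 higher and 1450 lower, the opposite balance) and 330 by DESeq2. The groups did not overlap in 21.6% of genes, against 10% by chance. Without control cross A or without maternal dose 2 C the count was 0, it was 36 without control cross C, and it was 45 and 30 without maternal dose 2 A and B. Lars2 had an edgeR adjusted p = 0.0671 without maternal dose 2 A. With the replicate letters as a block it was 297, and with the 6 libraries compared alone it was 40. Antisense and overlapping RNAs such as these are uncertain, because the strand setting of the counting and the annotation are not given in the sources used here.

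Ribosomal protein genes in the maternal dose 2 cross had a median of 0.12, with 27 of 29 members higher and 5 that rose when adjusted over the list alone, none over all genes (camera adjusted p = 2.95e-06; adjusted p = 0.926 with an estimated correlation). Elongating spermatid markers had a median of -0.10, with 22 of 27 lower and 3 that fell adjusted over the list alone (camera adjusted p = 0.00222; adjusted p = 0.926 with an estimated correlation). Smcp, a sperm mitochondrial capsule gene, had a change of -0.33. Cell cycle genes had a median of 0.09, with 2 that rose and 1 that fell adjusted over the list alone (camera adjusted p = 0.0277; adjusted p = 0.926 with an estimated correlation). Without control cross A, 1 of the 3 calls remained, and 2 remained without control cross C, maternal dose 2 A or maternal dose 2 C.

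In the F2 testis of the paternal dose 1 cross, Kit, the receptor of differentiating spermatogonia, was at 33.8 ± 1.72 CPM against 24.8 ± 0.95 in the control cross (n = 3 each) and rose by 0.45 (edgeR adjusted p = 0.0165), the 1 spermatogonia marker that passed over all genes. Another count, adjusted over the list alone, gave 6 markers that rose, among them Zbtb16 and Dmrt1. Spermatogonia markers had a median of 0.19, with 15 of 20 higher (camera adjusted p = 0.000187; adjusted p = 0.454 with an estimated correlation). Elongating spermatid markers had a median of -0.13, with 24 of 27 lower and 2 that fell adjusted over the list alone (camera adjusted p = 1.29e-05; adjusted p = 0.552 with an estimated correlation). Round spermatid markers had a median of -0.09, with 22 of 25 lower (camera adjusted p = 0.000777; adjusted p = 0.638 with an estimated correlation). Sertoli cell markers had a median of 0.13 (camera adjusted p = 0.000187; adjusted p = 0.454 with an estimated correlation). Smooth muscle, extracellular matrix, heat shock, DNA methylation, ribosomal protein and cell cycle genes were also called, with medians from 0.06 to 0.25 (camera adjusted p = 0.0125 to 0.0373; adjusted p = 0.454 to 0.796 with an estimated correlation). Kit had an edgeR adjusted p = 0.0555, 0.0674 and 0.0794 without control cross A, B and C, and 0.0541 and 0.124 without paternal dose 1 B and C. Of the 10 list calls, 4, 8 and 7 remained without control cross A, B and C, and 8, 6 and 6 without paternal dose 1 A, B and C.

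Cyp46a1, a cholesterol hydroxylase gene, was at 20.8 ± 2.39 CPM in the paternal dose 1 cross against 11.2 ± 1.51 in the control cross and rose by 0.89 (edgeR adjusted p = 0.0165). Sirt2, an NAD-dependent deacetylase gene, rose by 0.49 (189 ± 3.83 against 134 ± 4.27 CPM, edgeR adjusted p = 0.0132), and Ezr, the ezrin gene, by 0.57 (edgeR adjusted p = 0.0366). Lars2 fell by 2.36 (661.5 ± 448 against 3383 ± 484 CPM, edgeR adjusted p = 0.0123) and Malat1 by 1.52 (319.6 ± 80.1 against 919 ± 142 CPM, edgeR adjusted p = 0.00299). Rn45s, named after its values were seen, fell by 1.00 (edgeR adjusted p = 0.000352), and Gnasas1, an antisense RNA of the imprinted Gnas locus, by 1.16 (edgeR adjusted p = 0.0165). In all, 9 genes rose and 30 fell, with 2417 at an unadjusted p under 0.05 and 229 by DESeq2. The share of genes that did not overlap was 17.7%, against 10% by chance. The count was 5, 14 and 7 without control cross A, B and C, 3 and 6 without paternal dose 1 B and C, 84 with the replicate letters as a block and 15 with the 6 libraries alone. Lars2 had an edgeR adjusted p = 0.0551 and 0.082 without control cross A and paternal dose 1 B, and Sirt2 of 0.0517 to 0.0794 without any of control cross A, B or C or paternal dose 1 B or C.

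**Figure D2:**
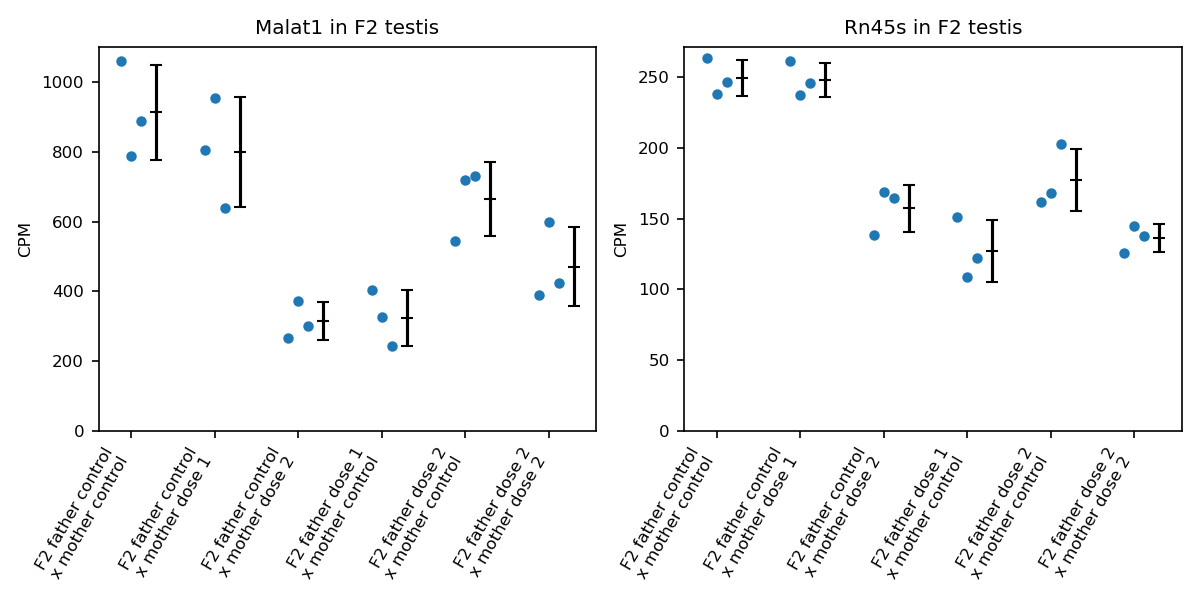
Malat1 and Rn45s in F2 testis, in CPM, with 1 point per library and bars at the mean of each cross ± SD. Rn45s lies at 238 to 263 CPM in the control cross and at 138 to 169 CPM in the maternal dose 2 cross, 108 to 151 CPM in the paternal dose 1 cross and 126 to 145 CPM in the biparental dose 2 cross.

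The transcript 1700001J04Rik was higher than in the control cross in each of the 5 F2 testis crosses with an exposed parent. These 5 comparisons share the same 3 control libraries, at 0.159 to 0.324 CPM, and are not separate results. Its change was 2.89 in the maternal dose 1 cross (1.72 ± 0.462 against 0.231 ± 0.0856 CPM, n = 3 each, edgeR adjusted p = 0.0474), 2.78 in the maternal dose 2 cross and 3.55 in the paternal dose 1 cross. It was 3.96 in the paternal dose 2 cross (edgeR adjusted p = 0.000394) and 4.01 in the biparental dose 2 cross (edgeR adjusted p = 0.000313). The F1 testis libraries spread from 0.157 to 6.77 CPM for this transcript, with the unexposed controls A and B at 2.69 and 2.95 CPM and control C at 0.169 CPM. In the maternal dose 1 cross Gins1, a subunit gene of the replication fork complex, rose by 0.88 (15.2 ± 1.53 against 8.27 ± 1.28 CPM, edgeR adjusted p = 0.0474). These 2 genes were those that passed there, with 1268 at an unadjusted p under 0.05 and 12 by DESeq2. By edgeR 0 passed without control cross A, B or C, without maternal dose 1 A or C, or with the replicate letters as a block, and 6 with the 6 libraries alone. Endothelial markers had a median of 0.12 in this cross (camera adjusted p = 0.0239; adjusted p = 0.599 with an estimated correlation). Their camera adjusted p was 0.227, 0.0883 and 0.102 without control cross B, maternal dose 1 B and maternal dose 1 C.

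In the F2 testis of the biparental dose 2 cross, 11 gene lists were called higher by camera (lowest adjusted p = 0.298 with an estimated correlation). Cholesterol synthesis and uptake genes had a median of 0.15, with 20 of 23 higher (camera adjusted p = 3.1e-06; adjusted p = 0.298 with an estimated correlation). Leydig cell markers had a median of 0.26, with 15 of 19 higher (camera adjusted p = 0.000154; adjusted p = 0.298 with an estimated correlation). Steroidogenesis genes had a median of 0.18, with 17 of 20 higher (camera adjusted p = 0.00244; adjusted p = 0.33 with an estimated correlation). Star, the cholesterol carrier of this pathway, was at 133 ± 19.4 against 93.7 ± 14.3 CPM (edgeR adjusted p = 0.621). Estrogen response genes had a median of 0.17, and Greb1 and Cxcl12 rose adjusted over the list alone (camera adjusted p = 0.00628; adjusted p = 0.298 with an estimated correlation). Sertoli cell, spermatogonia, PPAR target, xenobiotic metabolism, extracellular matrix, androgen response and endothelial genes had medians from 0.05 to 0.18 (camera adjusted p = 0.000932 to 0.0494; adjusted p = 0.298 to 0.505 with an estimated correlation). No list member passed over all genes. Of the 11 list calls, 9 and 5 remained without control cross A and B, and 8 and 5 without biparental dose 2 B and C. Single genes that passed were 1700001J04Rik, Gm9758, which fell by 1.08 (edgeR adjusted p = 0.0239), and Rn45s, which fell by 0.87 (137 ± 8.63 against 251 ± 14.1 CPM, edgeR adjusted p = 0.00127). There were 1360 at an unadjusted p under 0.05 and 32 by DESeq2, and by edgeR 9 passed with the block, 19 with the 6 libraries alone and 5 with no filter. Gm9758 had an edgeR adjusted p = 0.0927 and 0.198 without control cross A and C, and 0.15 and 0.108 without biparental dose 2 A and B.

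In the paternal dose 2 cross, 1700001J04Rik was the 1 gene that passed in F2 testis, with 972 at an unadjusted p under 0.05 and 8 by DESeq2; 3 passed with the block and 9 with the 6 libraries alone. Extracellular matrix genes had a median of 0.19 and elongating spermatid markers of -0.06, with 23 of 27 lower (camera adjusted p = 0.048 for both; adjusted p = 0.96 for both with an estimated correlation). Of these 2 calls, 0 remained without control cross A or paternal dose 2 B, and 1 without control cross B or paternal dose 2 C. Cyp11a1, Cyp17a1, Hsd3b1, Star, Cyp19a1, Esr1, Esr2 and Ptgs1, named before the data were examined, passed edgeR in none of the 7 testis comparisons with a control.

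Direct tests of parental origin in F2 testis asked whether a dose acted differently through the mother or the father. For dose 1, Rn45s (249 ± 12.6 against 125 ± 21 CPM, log2 change 0.99, edgeR adjusted p = 0.000424) and Malat1 (799.6 ± 154 against 319.6 ± 80.1 CPM, edgeR adjusted p = 0.0187) were higher in the maternal cross. Sirt2 was lower there (log2 change -0.44). In all, 5 genes were higher and 3 lower, with 2237 at an unadjusted p under 0.05 and 151 by DESeq2. This count was 27 with the replicate letters as a block and 2 with the 6 libraries alone. It was 1, 2 and 3 without maternal dose 1 A, B and C, and 15, 1 and 1 without paternal dose 1 A, B and C. Spermatogonia markers had a median of -0.21, and round and elongating spermatid markers both of 0.12 (camera adjusted p = 2.09e-06, 2.09e-06 and 4.82e-06), while the lowest adjusted p of any list was 0.145 with an estimated correlation. For dose 2, Greb1, an estrogen-responsive gene, was higher in the maternal cross (27.1 ± 0.709 against 19.6 ± 0.46 CPM, log2 change 0.47, edgeR adjusted p = 0.0429). Malat1 (log2 change -1.09) and Kcnq1ot1 (log2 change -0.78) were lower. In all, 9 genes were higher and 14 lower, with 3106 at an unadjusted p under 0.05 (1766 higher and 1340 lower, the opposite balance) and 470 by DESeq2. The count was 280 with the replicate letters as a block, 47 with the 6 libraries alone and 13 with RLE, 3 higher and 10 lower. By edgeR 2, 3 and 0 passed without maternal dose 2 A, B and C, and 0 without paternal dose 2 A or B. Ribosomal protein genes had a median of 0.12 (camera adjusted p = 8.3e-05), while the lowest adjusted p of any list was 0.899 with an estimated correlation.

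The F1 ovary libraries differed in their content of testis transcripts. Genes expressed in testis and absent from F2 ovary stood in control A at 8.91% of their testis level, and 8 Y-linked genes at 8.57%. The other F1 ovary libraries had 0.091% to 0.656% from the former genes and 0% to 0.7695% from the Y-linked ones, highest in dose 1 C and in dose 2 A and B. In F2 ovary these were low by the way they were chosen, while the Y-linked genes, chosen by name, stood at 0.0181% or less. Prm1, named after its values were seen, was at 251.5 CPM in control A and 2.37 to 16.6 CPM in the other F1 ovary libraries. Control A belongs to the reference group of both F1 ovary comparisons.

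**Figure D3:**
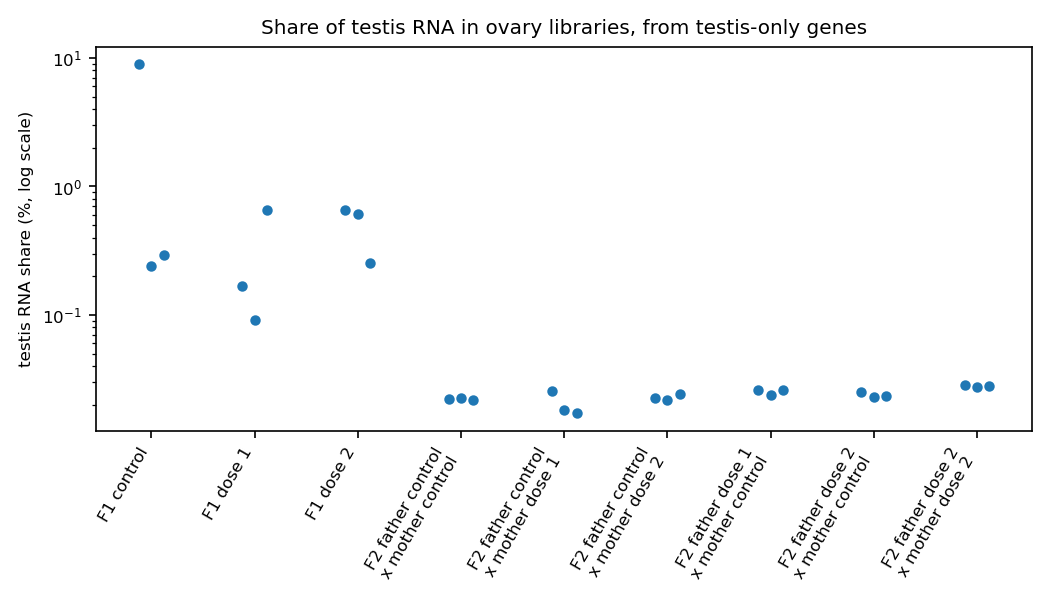
Share of testis RNA in each ovary library, in percent on a log axis, estimated from 541 genes expressed in testis only, with 1 point per library and libraries grouped by F1 exposure or F2 cross. Control A of F1 stands at 8.91%, above the range of 0.091% to 0.656% in the other F1 libraries, while the F2 libraries lie low by the choice of genes.

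In the F1 ovary at dose 1, oocyte markers were lower, with a median of -0.38 and 34 of 36 members lower. Of these, 8 fell adjusted over the list alone, 0 over all genes (camera adjusted p = 1.64e-14; adjusted p = 0.582 with an estimated correlation). The zona pellucida genes Zp1 and Zp2 were at 41.7 ± 5.38 and 139 ± 6.57 CPM against 57.5 ± 0.956 and 184.5 ± 6.67 CPM in controls (n = 3 each). Cholesterol synthesis and uptake genes had a median of 0.34, with 23 of 24 higher (camera adjusted p = 6.37e-08; adjusted p = 0.623 with an estimated correlation). Surface epithelium markers had a median of 0.49, with 16 of 16 higher, and endothelial markers of 0.22, with 15 of 15 higher (camera adjusted p = 1.32e-05 and 1.45e-06; adjusted p = 0.623 and 0.201 with an estimated correlation). Crip1 and Egfl7 rose adjusted over the lists alone. Heat shock, apoptosis, interferon, macrophage, theca and oxidative stress genes had medians from 0.09 to 0.25, and smooth muscle and oviduct markers of -0.15 and -0.76 (camera adjusted p = 0.00079 to 0.0498; adjusted p = 0.215 to 0.623 with an estimated correlation). Without control A, the library with the most testis transcripts, 7 of the 12 calls remained, with a camera adjusted p of 3.95e-16 for oocyte markers and 1.82e-05 for cholesterol genes. The oviduct call was lost without control A, dose 1 A or dose 1 B (camera adjusted p = 0.968, 0.0749 and 0.194). Apoptosis, oxidative stress, heat shock and theca genes also lost their call without control A (camera adjusted p = 0.0577, 0.303, 0.118 and 0.0763). The number was 10 and 9 without control B and C, and 9, 9 and 10 without dose 1 A, B and C. By edgeR 0 genes passed, with 1490 at an unadjusted p under 0.05 and 26 by DESeq2. The lowest edgeR adjusted p was 0.55, shared by many genes, among them Abca4 (30.2 ± 0.635 against 43.1 ± 5.28 CPM) and Egfl7.

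In the F1 ovary at dose 2, interferon response genes were higher, with a median of 0.70 and 23 of 24 members higher. Xaf1 and Gbp2 rose adjusted over the list alone, 0 over all genes (camera adjusted p = 2.63e-11; adjusted p = 0.477 with an estimated correlation). Surface epithelium markers and extracellular matrix genes had medians of 0.46 and 0.22 (camera adjusted p = 2.46e-08 and 2.65e-07; adjusted p = 0.477 for both with an estimated correlation). Granulosa cell markers had a median of -0.12 and heat shock genes of -0.20 (camera adjusted p = 0.00648 and 0.000636; adjusted p = 0.433 and 0.643 with an estimated correlation). Endothelial, macrophage, cholesterol and theca genes had medians from 0.11 to 0.18 (camera adjusted p = 0.000222 to 0.0448; adjusted p = 0.433 to 0.872 with an estimated correlation). Bmpr2, a receptor of bone morphogenetic proteins, was at 438 ± 13 CPM against 619 ± 16.7 (log2 change -0.50; adjusted p = 0.185 by edgeR and 2.44e-28 by DESeq2). The transcription factor gene Tcf21 was at 99.2 ± 1.54 against 71.6 ± 4.06 CPM (adjusted p = 0.185 by edgeR and 2.51e-10 by DESeq2). Without control A, 6 of the 9 list calls remained, with a camera adjusted p of 3.64e-07 for interferon genes. Cholesterol, theca and endothelial genes lost their call there (camera adjusted p = 0.3645, 0.2573 and 0.0639). The number of calls that remained was 6 and 7 without control B and C. It was 6 without dose 2 A, where theca markers had the opposite direction (camera adjusted p = 0.837). By edgeR 0 genes passed, with 671 at an unadjusted p under 0.05 and 8 by DESeq2, and 1 passed without dose 2 C.

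Between the doses in F1 ovary, oocyte markers had a median of 0.29 and heat shock genes of -0.31 at dose 2 relative to dose 1 (camera adjusted p = 9.48e-12 and 7.76e-10). Neither dose group holds control A, but it is among the 9 libraries fitted together and enters the estimated spread. The lowest adjusted p of any list was 0.655 with an estimated correlation. Dnaja1, a heat shock cochaperone gene, had a log2 change of -0.50 (adjusted p = 0.645 by edgeR and 3.4e-08 by DESeq2). By edgeR 0 genes passed, with 1077 at an unadjusted p under 0.05 and 57 by DESeq2, and 1 passed without dose 2 C.

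In the F2 ovary of the paternal dose 2 cross, cholesterol synthesis and uptake genes were lower in 24 of 24 members, with a median of -0.41. Of these, 13 fell adjusted over the list alone and 0 over all genes (camera adjusted p = 1.08e-22; adjusted p = 0.0172 with an estimated correlation). Dhcr7, the enzyme of the last step of cholesterol synthesis, was at 71 ± 4.45 CPM against 98.3 ± 10.8 in the control cross (n = 3 each). Targets of luteinizing hormone, follicle-stimulating hormone and prolactin were lower in 16 of 16 members, with a median of -0.22. Of these, 1 fell adjusted over the list alone and 0 over all genes (camera adjusted p = 1.34e-05; adjusted p = 0.0172 with an estimated correlation). The member that fell was Pappa, a protease of IGF-binding proteins, at 2.04 ± 0.347 against 8.32 ± 4.9 CPM. Lhcgr, the luteinizing hormone receptor, was at 112 ± 27.5 against 299 ± 133 CPM and Inhba, an activin and inhibin subunit, at 477 ± 21.9 against 924 ± 195 CPM. These were the 2 of 116 list calls in comparisons with a control that held with an estimated correlation, and both were kept in 10 of 10 alternatives. Apart from the estimated correlation itself, these alternatives used the preset correlation between genes. Leaving out libraries was not combined with an estimated correlation, so how far these calls depend on single libraries under it was not tested. The adjustment covered the lists of this comparison, not those of all comparisons. By edgeR 0 genes passed, with 664 at an unadjusted p under 0.05 and 7 by DESeq2.

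Also in the paternal dose 2 cross, steroidogenesis genes had a median of -0.19 and luteal markers of -0.20, with 4 luteal markers that fell adjusted over the list alone (camera adjusted p = 0.000133 and 3.75e-05; adjusted p = 0.135 and 0.108 with an estimated correlation). Oocyte markers had a median of 0.19 and adipocyte markers of 1.52, with 5 adipocyte markers that rose adjusted over the list alone (camera adjusted p = 3.75e-05 and 1.3e-06; adjusted p = 0.448 and 0.215 with an estimated correlation). Cell cycle, oviduct, ribosomal protein, smooth muscle and blood genes were called higher, and oxidative stress, heat shock, theca, macrophage and immediate early genes lower (camera adjusted p = 0.000106 to 0.0444; adjusted p = 0.215 to 0.643 with an estimated correlation). Without control cross A, ribosomal protein genes had the opposite direction (camera adjusted p = 0.0897). Of the 16 calls, 9, 11 and 13 remained without control cross A, B and C, and 14, 12 and 12 without paternal dose 2 A, B and C.

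In the F2 ovary of the maternal dose 2 cross, cholesterol synthesis and uptake genes had a median of -0.30, with 23 of 24 lower and 6 that fell adjusted over the list alone (camera adjusted p = 3.86e-12; adjusted p = 0.0927 with an estimated correlation). All F2 ovary crosses are compared with the same 3 control libraries, so list calls that recur across crosses are not separate results. Steroidogenesis genes had a median of -0.27, and 5 fell adjusted over the list alone (camera adjusted p = 8.6e-06; adjusted p = 0.0927 with an estimated correlation). Cyp11a1, the side-chain cleavage enzyme, was at 822.6 ± 126 CPM against 1981 ± 378 (n = 3 each, log2 change -1.27; adjusted p = 0.238 by edgeR and 0.000355 by DESeq2). Cyp17a1 was at 343 ± 146 against 1213 ± 157 CPM (edgeR adjusted p = 0.605). Macrophage markers were lower in 18 of 18 members, with a median of -0.56 (camera adjusted p = 1.22e-08; adjusted p = 0.237 with an estimated correlation). Oocyte markers were higher in 33 of 36, with a median of 0.34, and cell cycle genes in 25 of 25, with a median of 0.21 (camera adjusted p = 1.19e-09 and 1.05e-07; adjusted p = 0.283 and 0.138 with an estimated correlation). Theca and luteal markers, PPAR targets, xenobiotic metabolism, endothelial, interferon, immediate early, oxidative stress and hormone target genes were called lower and DNA methylation genes higher (camera adjusted p = 0.000166 to 0.0143; adjusted p = 0.0633 to 0.595 with an estimated correlation). Of the 15 calls, 12, 11 and 13 remained without control cross A, B and C, and 14, 13 and 14 without maternal dose 2 A, B and C. By edgeR 0 genes passed, with 1044 at an unadjusted p under 0.05 and 24 by DESeq2.

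In the F2 ovary of the paternal dose 1 cross, interferon response genes were lower in 24 of 24 members, with a median of -0.63, and Ifit3b and Irf9 fell adjusted over the list alone (camera adjusted p = 9.89e-14; adjusted p = 0.171 with an estimated correlation). Cell cycle genes were higher in 24 of 25, with a median of 0.34, and 9 rose adjusted over the list alone, among them Cdc20 and Ccnb2 (camera adjusted p = 1.65e-11; adjusted p = 0.162 with an estimated correlation). Cholesterol genes had a median of -0.19 and luteal markers of -0.25 (camera adjusted p = 2.75e-06 and 9.15e-05; adjusted p = 0.171 and 0.162 with an estimated correlation). Adipocyte markers had a median of 1.83 and oviduct markers of 1.00 (camera adjusted p = 2.29e-07 and 7.67e-11; adjusted p = 0.171 and 0.162 with an estimated correlation). Adipoq, an adipocyte hormone gene, was at 4.68 ± 4.21 CPM against 0.245 ± 0.0898. Granulosa, DNA methylation and smooth muscle genes were called higher, and macrophage, heat shock, immediate early, theca, oxidative stress, steroidogenesis, endothelial and hormone target genes lower (camera adjusted p = 9.15e-05 to 0.0334; adjusted p = 0.171 to 0.384 with an estimated correlation). The predicted gene Gm9199 was at 0.0532 ± 0.047 CPM against 3.28 ± 1.58 (log2 change -5.90, edgeR adjusted p = 0.00199). It was the gene that passed, with 864 at an unadjusted p under 0.05 and 21 by DESeq2. With the 6 libraries alone 0 passed, and 2 passed without paternal dose 1 A. Of the 17 list calls, 12, 12 and 15 remained without control cross A, B and C, and 16, 14 and 16 without paternal dose 1 A, B and C.

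**Figure D4:**
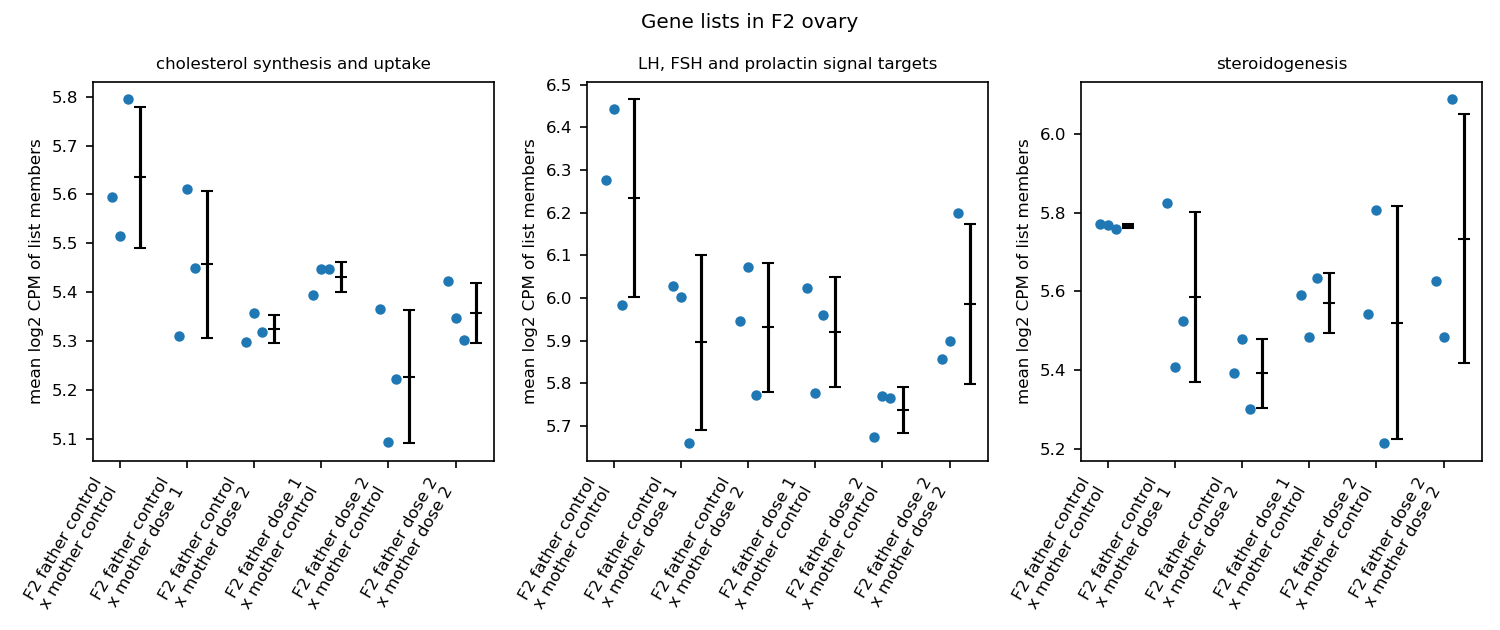
Mean level of the members of gene lists in F2 ovary, in log2 CPM, with 1 point per library, libraries grouped by cross and bars at the mean of each cross ± SD. Cholesterol synthesis and uptake genes lie lower in the paternal dose 2 cross than in the control cross, with 24 of 24 members lower.

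In the F2 ovary of the maternal dose 1 cross, theca markers had a median of -0.21, and Sfrp4, Cyp11a1, Fabp3 and Lhcgr fell adjusted over the list alone (camera adjusted p = 0.0315; adjusted p = 0.572 with an estimated correlation). Adipocyte and oviduct markers had medians of 1.52 and 0.62 (camera adjusted p = 0.0166 and 0.00502; adjusted p = 0.572 for both with an estimated correlation); Adipoq was at 3.38 ± 3.89 CPM against 0.245 ± 0.0898. Interferon and macrophage genes had medians of -0.31 and -0.33 and cell cycle genes of 0.19 (camera adjusted p = 0.0113, 0.0315 and 0.017; adjusted p = 0.572 to 0.652 with an estimated correlation). By edgeR 0 genes passed, with 2280 at an unadjusted p under 0.05 and 45 by DESeq2, but 1360 passed without maternal dose 1 A. Maternal dose 1 C stood apart from the other F2 ovary libraries at 97.3 on the first principal component, with Malat1 at 67.1 CPM where the others had 248 to 524. Of the 6 list calls, 4, 5 and 3 remained without control cross A, B and C, and 3 each without maternal dose 1 A or B.

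In the F2 ovary of the biparental dose 2 cross, cholesterol synthesis and uptake genes had a median of -0.24, with 20 of 24 lower, and 9 fell adjusted over the list alone, among them Dhcr7 (camera adjusted p = 6.48e-08; adjusted p = 0.317 with an estimated correlation). Ribosomal protein genes were higher in 29 of 29 members, with a median of 0.23, and oocyte markers had a median of 0.30 (camera adjusted p = 5.79e-06 and 6.37e-06; adjusted p = 0.705 and 0.675 with an estimated correlation). Oviduct markers had a median of 0.73, heat shock genes of -0.12, imprinted genes of -0.13 and hormone targets of -0.21 (camera adjusted p = 1.02e-05 to 0.0333; adjusted p = 0.317 to 0.534 with an estimated correlation). Adamts1, a protease of ovulation, was at 35.5 ± 3.67 CPM against 60.8 ± 8.33 (n = 3 each; adjusted p = 0.4 by edgeR and 0.000371 by DESeq2). By edgeR 0 genes passed, with 1566 at an unadjusted p under 0.05 and 23 by DESeq2. Of the 7 list calls, 5, 5 and 6 remained without control cross A, B and C, and 5, 6 and 6 without biparental dose 2 A, B and C.

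Direct tests of parental origin in F2 ovary found Gm9199 higher in the maternal than in the paternal dose 1 cross (4.70 ± 1.4 against 0.0532 ± 0.047 CPM, log2 change 6.42, edgeR adjusted p = 0.000645). It was the 1 gene that passed, with 2188 at an unadjusted p under 0.05 and 49 by DESeq2. By edgeR 0 passed with the 6 libraries alone, 1079 without maternal dose 1 A and 3 without paternal dose 1 A. No list was called for dose 1. For dose 2, edgeR called 0 genes, with 414 at an unadjusted p under 0.05 and 2 by DESeq2. Adipocyte markers had a median of -1.08 and macrophage markers of -0.36 in the maternal relative to the paternal dose 2 cross (camera adjusted p = 3.71e-06 and 0.000124). The lowest adjusted p of any list was 0.191 with an estimated correlation. Star, Cyp11a1, Cyp17a1, Hsd3b1, Cyp19a1, Esr1, Esr2, Ptgs1 and Ptgs2, the same genes with Ptgs2 added, passed edgeR in none of the 7 ovary comparisons with a control.

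With all 27 libraries of a tissue in a joint fit, edgeR called 2 genes in F1 testis at dose 1, 0 at dose 2 and 2 between doses, and 0 in each comparison of F2 testis and of ovary. The maternal dose 2 and paternal dose 1 crosses shared 2 higher and 16 lower genes in F2 testis, where independence gives 0.00464 and 0.096. Their fold changes correlated at 0.636 across genes, which are not independent replicates, against 0.506 in simulations with shared controls alone, and had a covariance of 0.0763 against 0.0356 simulated. An excess over these simulations was common to the crosses: 10 of 10 pairs of F2 testis crosses had a covariance above their highest simulated value, at 0.0468 to 0.0763. The same held for 8 of 10 pairs in F2 ovary, but 5 of the 10, 3 of these 8 among them, had a correlation under the simulated mean. The simulations drew genes independently, so they leave out structure common to the genes of a library, and the pairs reuse the same controls. Some or all of the excess may come from the shared controls, which at 3 libraries cannot be divided between the comparisons. In F1 testis the doses shared 0 called genes, and the covariance of 0.0656 was under the simulated 0.0689. In F1 ovary they shared 0 by edgeR, with a covariance of 0.133 against 0.125 simulated, under the highest simulated value of 0.139, and a correlation of 0.687 against 0.4996. Control A, with its testis transcripts, belongs to both of these F1 ovary comparisons. Between generations, only F1 dose 2 was set against the F2 biparental dose 2 cross. Their calls shared 0 genes in either tissue by edgeR, and 1 in testis by DESeq2; their fold changes correlated across genes at 0.125 in testis (rank correlation 0.0712). In ovary the correlation was -0.0272, 0.0147 with the replicate letters as a block, and 0.107 by ranks.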

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

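The tests of testis RNA in ovary (ratio and ovary expression), both tests of ribosomal and nuclear RNA carry-over and the test of an inherited variant were chosen only after the result was seen.

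A direct test between doses or between parents singled out these counts. In F1 testis 5 genes differed between dose 2 and dose 1. In F2 testis 8 genes differed between the maternal and paternal dose 1 crosses and 23 between the maternal and paternal dose 2 crosses. In F2 ovary 1 gene differed between the maternal and paternal dose 1 crosses.

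Control A of F1 ovary held the most transcripts of testis. Expression of these genes by the ovary is argued against by Y-linked genes at 473 times the highest share in F2 ovary, and a mislabelled testis by ovary-only genes at 111.9% of their level in the other F1 ovary libraries. Admixed testis RNA is a candidate explanation: the shares from Y-linked and from other testis genes had a ratio of 0.962 (0.5 to 2 was set as the range for a single source). The step at which such RNA may have entered is open.

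The F1 testis genes called at either dose (Crtam, Cck, Alms1-ps2, Gm11166 and P2rx5) did not overlap between the exposed and control libraries that called them. An inherited variant that segregates in the colony is a candidate explanation: 5 of the 5 genes spread within a single F2 group by at least 0.5 of their F1 log2 change, where on average 3.96% of genes of like level did (1% for Crtam to 12.4% for Alms1-ps2). Gm11166 was close to the bound, with a range of 1.41 against a change of -2.81. P2rx5 and Cck spread by 3.29 and 5.03 on the log2 scale among the 3 libraries of the F2 control cross, whose parents were unexposed. In that cross Crtam, Alms1-ps2 and Gm11166 spread by 0.391, 0.348 and 0.376, under the bound. These genes spread that far only in crosses with an exposed parent. A spread within a group can also come from other differences between samples, which this test does not tell apart from a variant. Exposure in F1 stays open and untested.

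Lower Malat1, Lars2, Rn45s and other RNAs in the maternal dose 2 and paternal dose 1 crosses of F2 testis may come from a different carry-over of ribosomal and nuclear RNA. Rn45s was also lower in the biparental dose 2 cross, at 126 to 145 CPM against 238 to 263 CPM in the control cross. It was at 162 to 203 CPM in the paternal dose 2 cross and at 237 to 261 CPM in the maternal dose 1 cross. Sample numbers in the titles follow the order of the crosses, so sample order and cross cannot be told apart. Low Malat1 was not limited to crosses with an exposed parent. Unexposed F1 testis controls, at 104 to 473 CPM, overlapped the maternal dose 2 and paternal dose 1 crosses. Rn45s in these controls, at 161 to 229 CPM, overlapped the maternal dose 2 cross but lay above the paternal dose 1 cross, at 108 to 151 CPM. Within groups, the genes that fell correlated with Rn45s at a median of 0.328 and 0.234, above the value that 5% of random gene sets exceeded (0.0831 and 0.113), but under the 0.5 that the explanation needed and over the 0.2 that would have excluded it. After removal of trends with transcript length and GC content, 9 of 40 and 18 of 26 called genes with a known length kept their call, and their median absolute log2 change went from 0.63 ± 0.61 to 0.57 ± 0.62 and from 0.66 ± 0.53 to 0.67 ± 0.53. The same genes refitted with no trend removed gave 26 and 12 calls, against 9 and 22; the test is void as to the whole pattern, because only 55.6% and 66.7% of called genes have a known length, and in the maternal cross calls ended while the median fell by little. In the paternal dose 1 cross 18 of 26 calls stayed. The number of calls also moved with the refit alone, so that count does not decide. The median did not fall, which for these 26 genes argues against a trend with length or GC. Such a trend stays open for the called genes without a known length and for the maternal dose 2 cross. Carry-over and parental exposure stay open for both crosses, the latter untested.

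Regrouping the 6 libraries of each comparison gives 10 splits, too few for a share under 0.05. The numbers of splits with a count as large as the real one include the real split itself, and with a real count of 0 they are 10 by construction. In F1 testis the number was 1 at dose 1 (real 4, highest other 1), 4 at dose 2 (real 1, highest other 3) and 1 between doses (real 5, highest other 0). In F2 testis the number was 2 for the maternal dose 1 cross (real 2, highest other 2), 1 for maternal dose 2 (real 72, highest other 1) and 1 for paternal dose 1 (real 39, highest other 0). It was 1 for paternal dose 2 (real 1, highest other 0), 1 for the biparental cross (real 3, highest other 1), 1 between the dose 1 parents (real 8, highest other 2) and 1 between the dose 2 parents (real 23, highest other 0). In F1 ovary it was 10 for each comparison, as it had to be (real 0, highest other 0, 2 and 3). In F2 ovary it was 10 for maternal dose 1 (real 0, highest other 1192), 10 for maternal dose 2 (real 0, highest other 1), 1 for paternal dose 1 (real 1, highest other 0) and 10 for paternal dose 2 (real 0, highest other 0). It was 10 for the biparental cross (real 0, highest other 4), 1 between the dose 1 parents (real 1, highest other 0) and 10 between the dose 2 parents (real 0, highest other 0). The split with 1192 genes put control cross A, control cross C and maternal dose 1 B together. Maternal dose 1 C, which stood apart on the first principal component, was on the other side. What gave this count was not tested.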

How the results depend on the processing

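The fits without libraries that stand apart were chosen only after the data were seen; there, a group left with 1 library is assumed to vary like the other groups. Depth, at 31.6 M counts or more per library, limits the genes under the filter of 10 counts, and n = 3 limits every call. No named gene changed direction where it passed in the main analysis or the alternative (0 of 692 results), but 111 of the 1945 other results had the opposite sign. Of the 55 named values that passed, 51 still passed with RLE, 55 with no filter, 53 with the replicate block, 24 with the 6 libraries alone and 1 with all 27 libraries, and 51 of 51 with DESeq2, which gained 22. Leaving out 1 library kept 149 such calls, lost 181 and gained 3. Of 116 list calls, 2 held with an estimated correlation, 114 with RLE and 109 with the replicate block. Of 696 list results without 1 library, 519 were kept, 174 lost and 3 reversed. Of 89 without the libraries that stand apart, 78 were kept, 10 lost and 1 reversed. The cause was not tested for any change given here, except that leaving out libraries leaves fewer samples by construction.

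DESeq2 called more genes in each comparison. In F1 testis it called 27 at dose 1, 5 at dose 2 and 23 between doses. In F2 testis it called 12 and 330 in the maternal dose 1 and 2 crosses, 229 and 8 in the paternal ones, 32 in the biparental cross, and 151 and 470 between parents. In F1 ovary it called 26, 8 and 57. In F2 ovary it called 45 and 24 in the maternal crosses, 21 and 7 in the paternal ones, 23 in the biparental cross, and 49 and 2 between parents. Calls shared by pairs of comparisons with the same controls came to 29 by edgeR and 152 by DESeq2, summed over pairs, so a gene can count more than once. Between F1 dose 2 and the F2 biparental cross, the one pair of generations compared, they came to 0 and 1.

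RLE called 13 genes between the dose 2 parents in F2 testis, 3 higher and 10 lower, against 23 with 9 higher and 14 lower by TMM. No filter on low counts gave 5 genes in the biparental cross of F2 testis. With the 6 libraries alone the F1 testis count at dose 1 was 8; in F2 testis the counts were 6 and 40 in the maternal crosses, 15 and 9 in the paternal ones, 19 in the biparental cross, and 2 and 47 between parents. In F2 ovary they were 0 in the paternal dose 1 cross, 0 between the dose 1 parents and 1 between the dose 2 parents. All 27 libraries gave 2, 0 and 2 genes in F1 testis, and 0 in each comparison of F2 testis and of ovary. Without the libraries that stand apart, F1 testis gave 8 at dose 1. The dose 2 group was left with dose 2 A alone, so no counts are given for it.

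The replicate letters were not taken as pairs: same-letter correlations had means of 0.013 and 0.033 in F1 and F2 testis and -0.079 and -0.0039 in ovary, and exceeded 0.1 in 2 of 9, 5 of 45, 3 of 9 and 5 of 45 pairs. In F2 testis, though, 12 of 18 libraries correlated best with their own letter, and other letters had a mean of -0.0164, so a weak common structure there stays open. The other sets had 3 of 9, 2 of 9 and 3 of 18 such libraries. As a block the letters gave 0 and 297 genes in the maternal crosses of F2 testis, 84 and 3 in the paternal ones, 9 in the biparental cross, and 27 and 280 between parents, and a sum of 63 shared calls; no other count moved by over 1.5 times.

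Leaving out 1 library gave these ranges. In F1 testis they were 1 to 7 at dose 1, 1 to 4 at dose 2 and 3 to 7 between doses. In F2 testis they were 0 to 3 and 0 to 67 in the maternal crosses, 3 to 53 and 1 to 1 in the paternal ones, 2 to 4 in the biparental cross, and 1 to 15 and 0 to 19 between parents. In F1 ovary they were 0 to 0, 0 to 1 and 0 to 1. In F2 ovary they were 0 to 1360 and 0 to 0 in the maternal crosses, 1 to 2 and 0 to 0 in the paternal ones, 0 to 0 in the biparental cross, and 1 to 1079 and 0 to 0 between parents. Called lists numbered 105 to 122.

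Lists that reversed were ribosomal proteins in F1 testis at dose 2 without dose 2 C (camera adjusted p = 0.439; range over alternatives 8.7e-07 to 0.875) and adipocyte markers there without the libraries that stand apart (0.87; range 0.000762 to 0.87). Theca markers in F1 ovary reversed at dose 2 without dose 2 A (camera adjusted p = 0.837; range 0.000602 to 0.837), and ribosomal proteins in F2 ovary of the paternal dose 2 cross without control cross A (camera adjusted p = 0.0897; 2.34e-12 to 0.288 without 1 library, and up to 0.643 over alternatives).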

Other observations

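No test here was chosen after the result was seen. Among lists with no call, prostaglandin and leukotriene genes, which hold the targets of ibuprofen and diclofenac, had medians of -0.04 to 0.21 over the 7 testis comparisons with a control (lowest camera adjusted p = 0.0673) and of -0.13 to 0.08 in ovary (lowest camera adjusted p = 0.0882). Estrogen response genes had medians of -0.08 to 0.07 in ovary (lowest camera adjusted p = 0.0956), androgen response genes of -0.33 to 0.17 (0.239) and ovulation genes of -0.13 to 0.05 (0.2). In testis, spermatocyte markers had medians of -0.18 to 0.02 (lowest camera adjusted p = 0.0673), imprinted genes of -0.11 to 0.09 (0.372), macrophage markers of -0.08 to 0.20 (0.0884) and epididymis markers of 0.02 to 0.31 (0.403). Oxidative stress, apoptosis and immediate early genes in testis had lowest camera adjusted p = 0.0884, 0.176 and 0.0673.

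Library C of the maternal dose 1 cross in F2 ovary had Xist at 173.9 CPM, where the highest F2 ovary library had 943.2 CPM. Library C of the biparental dose 2 cross stood apart at 62.4 on the second principal component of F2 ovary, with Jchain, Saa3, Ly6i and Ccl5 among the genes that set it apart. In F1 ovary the first principal component held 64.1% of the variance. Control A stood apart on it at -136.2, where the others had -13.85 to 60.01, and testis genes such as Theg, Tex55, Actl7b and Tsks were among those at its end. In F1 testis the first component held 42.6%. In the paternal dose 2 cross of F2 testis Rn45s ran from 162 to 203 CPM. Malat1 ran there from 543 to 732 CPM, between the levels of the control cross (789 to 1060 CPM for Malat1) and of the maternal dose 2 cross (267 to 373 CPM).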
